A study of Rattus norvegicus with 3 samples.

How the data were processed

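Kidney RNA from 3 male rats was hybridised to Clariom S rat arrays, 1 array per rat: 1 control rat, 1 rat at day 2 and 1 rat at day 5 of ethylene glycol (EG) given orally at 8 g/kg. One label reads as a treatment lasting 2 or 5 days and another as sampling 2 or 5 days after treatment, so a single dose and repeated doses cannot be separated here. RNA was isolated with a column kit and labelled with biotin, per the labels' protocols.

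The authors summarised the probes into 1 log2 signal per transcript cluster (the probes assigned to 1 transcribed locus) with Transcriptome Analysis Console, per the file headers and the submitters' processing notes. The file headers give the rat annotation of genome build rn6 and no filter. The version of the program, the background correction, the summarisation and the normalization between arrays are not given in the sources used here. The deposited log2 values carry 2 decimals, and the column names call them averages without saying of what. Both deposited tables held identical values, 69564 of 69564 compared. The values reach 19.93, and 232 clusters exceed 16 log2 units, the range of a 16-bit scanner. Some transformation therefore set the scale, and 9 clusters sit at 19.9 or more on all arrays. Every fold below is on this deposited log2 scale, which can stretch or compress the difference in RNA, most of all for bright genes.

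Of 23188 clusters, 21502 named 1 gene, 1673 named several and 13 named none. Clusters naming several genes or none were left out, and a gene was represented by its brightest cluster over the 3 arrays, which gave 20667 genes, 776 of them with more than 1 cluster. Among 316 genes with at least 2 measured clusters, 40 had clusters that disagreed by more than 1 log2 unit, and none of the 265 genes chosen for naming was among them. Probes of close relatives, such as the globins, the Akr1b genes and the MHC genes, can share signal, so the values of single members are uncertain. Symbols are those of the files. A RefSeq gene table of assembly GRCr8 was used only to match older symbols. It held 16215 of the symbols as current ones and a further 1995 as older ones. No coordinates are given, since that assembly is not the build of the files.

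The background level was the 95th percentile of the values of 1160 olfactory receptor genes, taken to be silent in kidney, and came to 5.33 log2. Values under it were set to it. A gene was called measured where at least 1 array reached the level, which held for 13573 genes (65.7%). The control, EG day 2 and EG day 5 arrays had 12774, 12634 and 12824 genes at or above the level. A difference with 1 side under the level is a lower bound, written as at least N-fold, and a gene with both sides under it has no fold. In a list median or mean, a measured member with both sides under the level counts as 0. Without the floor, 5.10%, 5.29% and 3.59% of olfactory receptor genes lay 2-fold or more apart in the 3 comparisons. The number of arrays limits the precision.

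With 1 array per group there is no spread between animals, so no test was run and no p-value is given. A difference describes these 3 arrays and has no replicate check. Genes at least 2-fold and at least 4-fold apart were counted per direction. These counts were set beside 100 simulated draws of 3 unchanged arrays with normal noise. The noise SD per expression bin (0.25 to 0.38 log2) came from the median absolute difference between arrays. The smaller of EG day 5 against EG day 2 and EG day 2 against control was used. Treatment adds to that difference, so this noise is not a measured technical error. All genes of a bin share the same SD, so genes that vary more between rats are not covered. The simulation therefore cannot show that 4-fold or opposite differences exceed the variation between rats. The simulation also gave the overlap, correlation and covariance that a shared control array produces with no effect.

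Before the data were examined, 42 gene lists for pathways and cell types were fixed, together with the background rule, the alternatives and the rule for named genes. Of 1004 list members, 34 were not matched, 25 of these because they stand on clusters naming several genes. For each of the 40 lists with at least 5 measured members, the median log2 difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list outside percentiles 2.5 to 97.5 is said to stand apart. Chance puts 5% of lists of independent genes there, or 6.0 of the 120 results, and members of a list vary together, so more would fall outside by chance. The percentile describes these arrays, not the treatment. The named genes are the 10 largest differences in each direction from control for each time point, the 5 largest lower bounds in each direction, the 6 largest in each direction between the time points, up to 4 members of each list with the largest differences from control, and 10 genes fixed by name. Members outside this rule are named only where the text says so. Not every gene that the rule selects is reported here.

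The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The alternatives were quantile normalization, median centring, cyclic loess (limma 3.58.1 in R 4.3.3), other background levels, the mean of a gene's clusters, the other deposited table, lists without members shared with other lists, and the mean of a list. The steps were tested on simulated data for EG day 2 minus control with 13537 genes. Of 50 genes per size, 88% of those set 1.5 log2 units apart and 98% of those set 2 units apart were counted at 2-fold. Of 200 unchanged lists 9 fell outside the middle 95%, and 49 of 50 lists raised by 0.5 log2 units were found.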

Results

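Genome-wide transcript signals were obtained from whole kidney of 3 male rats, with 1 control array, 1 array at day 2 and 1 array at day 5 of ethylene glycol (EG). EG is an antifreeze solvent that the body oxidises to glycolate and oxalate, and oxalate precipitates with calcium as crystals in the kidney tubule. Array medians were 6.21, 6.26 and 6.30 log2 on the control, EG day 2 and EG day 5 arrays. Across genes, which are not independent replicates, Pearson's r was 0.974 for EG day 2 and control, 0.972 for EG day 5 and control, and 0.978 for both EG arrays. By the study's own description each value below comes from 1 rat, so no difference could be set against a spread between animals.

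The study's title names stone formation and tubular injury linked to complement and fibrinogen, and the comparison of EG day 2 with control shows which kidney transcripts differed at the earlier time. Havcr1, which encodes the tubular injury marker KIM-1, was at 5.92 log2 in the control and 18.39 at EG day 2, a difference of 12.47 (5673-fold on the deposited scale). Clu (clusterin) was higher by 7.66, Lcn2 (the injury marker NGAL) by 6.89 and Spp1 (osteopontin, a protein of stone matrix) by 6.56 log2 units. Of 23 measured members of the tubular injury list, 14 were at least 2-fold higher and 0 lower, with a median difference of 1.81 (percentile 100 of random lists). Vim was higher by 2.72, Tnfrsf12a by 3.22 and Timp1 by 2.61. On the same array the macrophage and monocyte list had a median of 1.18 and the proximal tubule list one of -0.61. Umod, the uromodulin gene of the thick ascending limb, was at 18.79 in the control and 18.69 at EG day 2. These values lie close to the highest value of 19.93, where differences can be compressed, so an unchanged transcript is not shown.

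Fibrinogen chain transcripts were among the largest differences at EG day 2. Fga was at 7.72 log2 in the control and 16.49 at EG day 2 (437-fold), and Fgb was at 6.06 and 13.83 (218-fold). Fgg was under the background level in the control and at 9.73 at EG day 2, at least 21.1-fold higher. The whole list of fibrinogen, coagulation and fibrinolysis genes had 7 of 28 measured members at least 2-fold higher and 2 lower, with a median of 0.23 (percentile 95.1), so it did not stand apart. With the background at the median of all values it was 0.30 (percentile 98.5), outside the middle range. Its mean was 0.97, carried by the fibrinogen genes and Kng1 (2.44, kininogen), and as a mean it lay at percentile 100. F10 (coagulation factor X) was at least 2.2-fold lower. Of 11 measured acute phase genes 6 were at least 2-fold higher and 0 lower, with a median of 1.16 (percentile 100). They included Serpina3n, a serine protease inhibitor (5.99), Socs3, a feedback inhibitor of cytokine signalling (4.0), and Osmr, the oncostatin M receptor (2.02).

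Some complement genes were higher, by smaller amounts than the fibrinogen chains, and others were not (quartiles of the list -0.085 and 0.735). C3, the central complement component, was at 5.44 log2 in the control and 7.96 at EG day 2, a 5.74-fold difference. C7 was higher by 1.52 and C1qb by 1.27, and 4 of 27 measured members were at least 2-fold higher and 0 lower. The list median was 0.48 (percentile 99.96). With the background at the median of all values it was 0.23 (percentile 95.2), which no longer stood apart. Complement and fibrinogen are named in the title of the study, so these lists are not independent of it. C2, C4a, Cfb and Masp1 stand on clusters that name several genes and were not analysed here. The macrophage and monocyte median of 1.18 stood on the same array.

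Macrophage and monocyte genes at least 2-fold higher numbered 15 of 24 at EG day 2, and 0 were lower. Msr1, a scavenger receptor, was higher by 1.84, Lyz2 (lysozyme) by 1.67 and Ccr2, a chemokine receptor, by 1.64. The neutrophil list had only 5 measured members and a median of 0.65 (percentile 99.06), and one of the members, Lcn2, is also made by injured tubules. With the background at the median of the olfactory receptor genes its median was 0.01 (percentile 71.1). T and NK cell genes (-0.03) and B and plasma cell genes (0.32) did not stand apart. Of 28 genes for chemokines, cytokines and adhesion, 6 were higher and 1 lower (median 0.38, percentile 99.8), among them Lif (at least 4.53-fold) and Ccl20 (1.6). Ptgs2, the inducible cyclooxygenase of that list, was lower by 2.48.

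Transporters and enzymes of the proximal tubule were lower at EG day 2. Of 41 measured members 11 were at least 2-fold lower and 2 higher, with a median of -0.61 (percentile 0). Slc5a12, a lactate transporter, differed by -1.63, Acsm3 by -1.25 and Slc34a1, the main renal phosphate transporter, by -1.16. The exceptions were the sulphate transporter Slc13a1 (1.75) and Slc22a13 (1.28). Slc34a2, a phosphate transporter of other epithelia, was higher by 3.93. Slc23a1, a vitamin C transporter, and Acmsd, an enzyme of tryptophan breakdown, differed by -2.47 and -1.95. Genes of EG, glyoxylate and oxalate metabolism had 2 of 22 members at least 2-fold lower and 1 higher, with a median of -0.45 (percentile 0.03), Adh1 (alcohol dehydrogenase) at -1.61 and Ldha (lactate dehydrogenase A) at 1.43. The macrophage median of 1.18 and a red blood cell median of -0.68 stood on the same array.

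Lists of other nephron segments had smaller median differences than the proximal tubule list (-0.61), although single members differed by as much. The thick ascending limb and distal tubule list had a median of -0.37 (percentile 0.20), although 3 of its 22 measured members were at least 2-fold higher and 2 lower. The prostaglandin receptor gene Ptger3 (1.93), Cldn19 (1.73) and Trpv5 (1.69) were higher, and Egf stood at -1.21. As a mean its value was -0.13 (percentile 10.7), inside the middle range. Intercalated cell genes had 1 of 17 members lower, 0 higher and a median of -0.23 (percentile 2.26), which cyclic loess moved to -0.10 (percentile 22.1). Principal cell genes (0.03), inner medulla and tonicity genes (-0.01), podocyte genes (0.22) and endothelial genes (0.02) did not stand apart. Liver parenchyma genes had a median of 0.28 (percentile 92.0). The adrenal cortex and urothelium lists had 1 and 2 measured members, too few for a median.

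Genes of crystal binding and stone matrix were higher at EG day 2, with 11 of 25 at least 2-fold higher, 0 lower and a median of 0.98 (percentile 100). Besides Spp1 these included S100a11 (2.54), the hyaluronan receptor gene Cd44 (2.36) and Anxa2 (2.08), and Spp1, Cd44 and Anxa2 are also on the tubular injury list. Cell cycle genes had 12 of 34 members at least 2-fold higher and 1 lower, with a median of 0.76 (percentile 100). Hmmr was higher by 1.52, and the replication helicase genes Mcm6 and Mcm4 by 1.42 and 1.34. Macrophage markers stood at 1.18 on the EG day 2 array. Immediate early genes included the largest lower value, Egr1, a transcription factor induced within minutes of a stimulus, at 16.48 in the control and 13.48 at EG day 2. Nr4a1 of the same list differed by -2.27.

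In all, 604 genes were at least 2-fold higher and 332 lower at EG day 2 than in the control, and 50 and 12 were at least 4-fold apart. Simulated unchanged arrays gave means of 226 higher and 225 lower at 2-fold, and 0.20 and 0.24 at 4-fold. Many 2-fold differences are therefore of the size that the simulated noise gives. That noise was taken from differences between these same arrays, to which treatment adds, so the share due to noise alone is not known. The share of higher genes among the 2-fold differences was 64.5%, and quantile normalization gave 54.1%. The lower genes numbered 503 with the background at the median of the olfactory receptor genes and 601 with no background level, where the shares of higher genes were 59.5% and 57.1%.

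**Figure D1:**
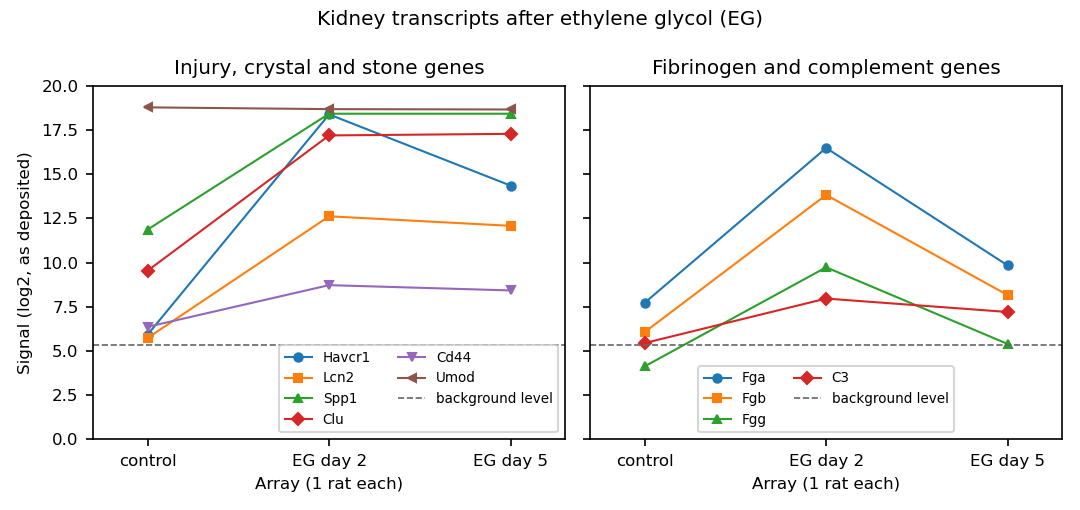
Log2 signal as deposited (vertical axis) on the control, EG day 2 and EG day 5 arrays (horizontal axis, 1 rat each) for the genes fixed by name, with the background level of 5.33 dashed. Points are single arrays and lines join the same gene across different rats. Havcr1 and the fibrinogen genes peak at EG day 2, Spp1 stays at 18.43 on both EG arrays, and Umod lies between 18.67 and 18.79. Differences between values as bright as those of Spp1 and Umod can be compressed.

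The comparison of EG day 5 with control shows which transcripts differed at the later time. Injury genes were again far higher: Havcr1 by 8.44, Clu by 7.75, Spp1 by 6.56 and Lcn2 by 6.35 log2 units. Of the 23 measured tubular injury members 17 were at least 2-fold higher and 1 lower, with a median of 1.34 (percentile 100). The stone matrix list had 11 of 25 members higher and 1 lower and a median of 0.53 (percentile 100), led after Spp1 by S100a11 (2.89), Fn1 (fibronectin, 2.51) and Mgp, an inhibitor of calcification (2.08). Macrophage markers stood at 1.28 and proximal tubule genes at -0.69 on this array.

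Genes of extracellular matrix and fibrosis had 21 of 34 members at least 2-fold higher and 1 lower at EG day 5, with a median of 1.08 (percentile 100). At EG day 2 the numbers were 9 and 2, with a median of 0.55 (percentile 100). Mmp2, a matrix-degrading protease, was higher by 2.45 at EG day 5, and the collagen genes Col3a1 and Col1a1 by 2.36 and 2.17. Fibroblast markers, which share Col1a1, Col3a1 and Dcn with that list, had 4 of 11 members higher and 1 lower at EG day 5, with a median of 0.75 (percentile 99.98), against 0.15 at EG day 2. Without members shared with other lists the EG day 2 median of the fibroblast list was -0.44 (percentile 0.70), so its direction at that time is not settled. Nt5e of the fibroblast list differed by -2.04. Smooth muscle and pericyte genes, with 4 of 12 higher and 0 lower, had a median of 0.51 (percentile 99.6) at EG day 5 and 0.21 at EG day 2. Without members shared with other lists the EG day 5 median was -0.11 (percentile 17.1), so that list has no settled direction. Fat tissue markers stood at 0.47 (percentile 98.3) at EG day 5 and -0.03 at EG day 2, with Fabp4 (1.11) and Adipoq (1.05) among the higher members. The macrophage median of 1.28 stood on the EG day 5 array.

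Complement genes had 8 of 27 members at least 2-fold higher and 1 lower at EG day 5, with a median of 0.55 (percentile 100). C7 was higher by 2.13, C1s by 1.85, C3 by 1.76 and C4b by at least 3.29-fold. The fibrinogen, coagulation and fibrinolysis list had 6 of 28 higher and 3 lower, with a median of 0.10 (percentile 80.7). Fga and Fgb were higher than in the control by 2.12 and 2.10, and Fgg, at 5.39, lay just over the background level. A2m, a protease inhibitor of the rat acute phase, was at least 5.35-fold higher, and F3 (tissue factor) was lower by 1.65. Acute phase genes had 6 of 11 higher and 0 lower, with a median of 1.23 (percentile 100). The title of the study names complement and fibrinogen, and macrophage markers stood at 1.28 on the same array.

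Macrophage and monocyte genes had 14 of 24 members at least 2-fold higher and 0 lower at EG day 5 (median 1.28, percentile 100), with Mrc1 (2.03), Lyz2 (1.94) and Adgre1 (1.87). Genes of MHC class II presentation had 3 of 10 higher and 0 lower (median 0.75, percentile 99.98), against a median of 0.12 at EG day 2. RT1-Ba was higher by 1.75 and Cd74, the invariant chain, by 1.34. Interferon response genes had 4 of 24 higher and 0 lower (median 0.59, percentile 100), against a median of -0.15 (percentile 3.29) at EG day 2, which was -0.26 (percentile 0.55) with the lower background. Irf7, a transcription factor of that response, was higher by 1.82. The neutrophil list had a median of 0.98 (percentile 99.96), again lost with the lower background (0.07). T and NK cell genes (-0.02), B and plasma cell genes (0.15) and chemokine genes (0.09) did not stand apart, although Cd4 was higher by 2.01.

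Proximal tubule genes at EG day 5 had 11 of 41 members at least 2-fold lower and 1 higher, with a median of -0.69 (percentile 0). Random lists matched to this list had a median of -0.16 at EG day 5 and 0.0 at EG day 2, so part of the EG day 5 value is shared by genes of like signal. Slc5a12 differed by -2.97, the bicarbonate transporter gene Slc4a4 by -2.08, the amino acid transporter gene Slc6a19 by -1.99 and the glucose transporter gene Slc5a2 by -1.84. Genes of EG, glyoxylate and oxalate metabolism had a median of -0.33 (percentile 5.32), with Adh1 at -2.35. The thick ascending limb and distal tubule list stood at -0.34 (percentile 3.77), and at -0.46 (percentile 1.31) without shared members. Intercalated cell (-0.12), principal cell (0.22), inner medulla (0.02), podocyte (0.15), endothelial (0.12) and liver parenchyma (0.16) lists did not stand apart. The liver median was 0.35 (percentile 99.2) with the lower background. Single members still differed, with 3 of 16 principal cell genes at least 2-fold higher and 0 lower, Gata3 (1.75) among them. For the inner medulla these numbers were 3 of 12 and 0, with Akr1b1 at 1.64 and Slc14a1 at 1.22. Red blood cell genes had a median of -1.06 (percentile 0) at EG day 5 and -0.68 (percentile 0) at EG day 2, with Hbb (beta globin) at -3.24 at EG day 5.

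In all, 645 genes were at least 2-fold higher and 491 lower at EG day 5 than in the control, and 44 and 46 were at least 4-fold apart. Simulated unchanged arrays gave means of 223 and 227 at 2-fold, and 0.23 and 0.21 at 4-fold. The share of higher genes was 56.8%, and centring each array on its median gave 43.3%, so which direction was more frequent depends on the scaling.

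**Figure D2:**
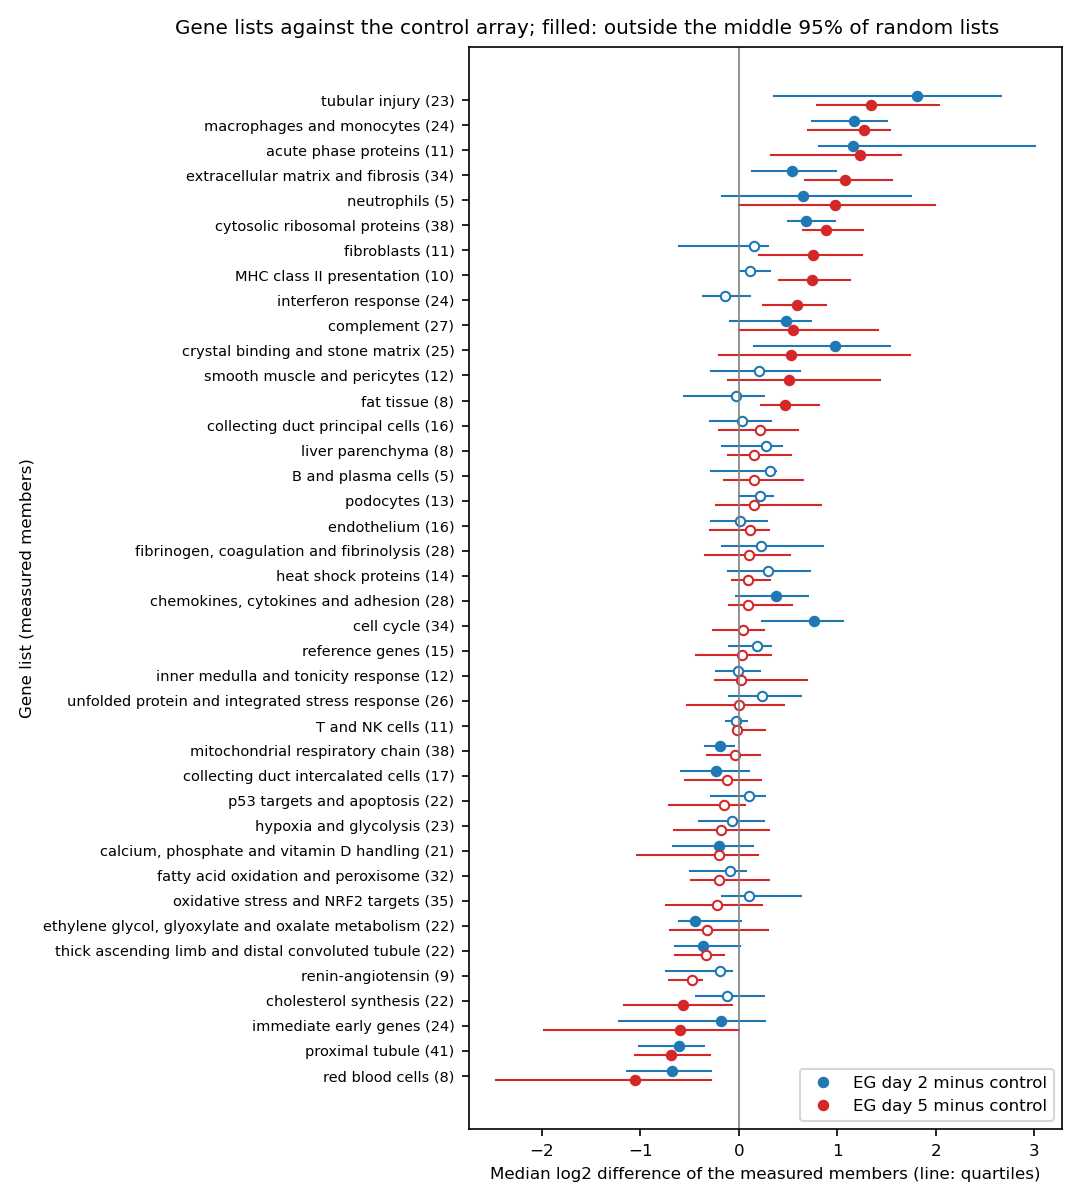
Median log2 difference from the control array (horizontal axis) of the measured members of 40 gene lists (vertical axis, number of measured members in brackets), with EG day 2 in blue and EG day 5 in red. Lines span the quartiles of the members in 1 array pair, not an error between animals, and filled points lie outside the middle 95% of matched random lists; tubular injury (1.81 and 1.34) lies at the top and red blood cells (-0.68 and -1.06) at the bottom.

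The direct comparison of EG day 5 with EG day 2 shows what differed between the time points without the control array. The fibrinogen genes were much lower at EG day 5: Fga by 6.65 (100-fold), Fgb by 5.67 and Fgg by 4.34 log2 units. Serpina3n differed by -4.76, Havcr1 by -4.03 and Btg2, a growth-suppressing gene, by -3.19. Dbp, a transcription factor of the circadian clock, was higher by 3.84, Car3 by 3.39 and the microfibril gene Mfap4 by 3.18. The fibrinogen, coagulation and fibrinolysis list had 1 of 28 members higher and 7 lower. Its median of 0.08 and its mean of -0.74 differed in sign, and the mean lay at percentile 0. With the background at the median of the olfactory receptor genes the median was 0.18 (percentile 97.7). Acute phase genes had 1 of 11 higher and 3 lower, with a median of -0.40 (percentile 1.61). With the lower background this was -0.24 (percentile 3.42), inside the middle range.

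Cell cycle genes had 9 of 34 members at least 2-fold lower and 1 higher at EG day 5 than at EG day 2, with a median of -0.75 (percentile 0). Against the control their EG day 5 median was 0.05 (percentile 42.9). Ccnd1 (cyclin D1) went the other way, higher by 1.42. Interferon response genes had 8 of 24 higher and 0 lower (median 0.71, percentile 100), with Mx2 at 2.42 and Irf7 at 1.97. Part of this is a lower EG day 2 array, where 3 of 24 members were at least 2-fold lower than in the control and 0 higher. Against control Mx2 was at -1.48 at EG day 2 and 0.94 at EG day 5, and Irf7 at -0.15 and 1.82. MHC class II genes had 4 of 10 higher and 0 lower (median 0.42, percentile 99.8). Matrix genes had 8 of 34 higher and 2 lower (median 0.41, percentile 100), fibroblast genes 5 of 11 higher and 0 lower (median 0.48, percentile 99.94), and smooth muscle genes 1 of 12 higher and 0 lower (median 0.44, percentile 99.94). Fat tissue genes stood at 0.51 (percentile 99.8), and at 0.34 (percentile 97.0) without shared members. Complement genes had 0 of 27 higher and 1 lower, and a median of 0.31 (percentile 99.95). Their mean was 0.15 (percentile 96.9), inside the middle range. Red blood cell genes had a median of -0.45 (percentile 0.83), and -0.07 (percentile 36.8) with the lower background. Tubular injury (-0.07), macrophage (0.06), stone matrix (-0.14) and proximal tubule (-0.08) medians did not stand apart between the time points in the main setting. As a mean, tubular injury was at -0.34 (percentile 1.23), and with the lower background the macrophage median was 0.27 (percentile 99.3), both outside the middle range.

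Between the time points 300 genes were at least 2-fold higher and 452 lower at EG day 5, and 13 and 30 were at least 4-fold apart. Simulated unchanged arrays gave a mean of 229 in each direction at 2-fold, and 0.26 and 0.29 at 4-fold. The share of higher genes among the 2-fold differences was 39.9%, and over the alternatives it ranged from 34.3% with median centring to 48.0% with quantile normalization. With no background level 510 genes were higher, and the share was 46.2%.

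**Figure D3:**
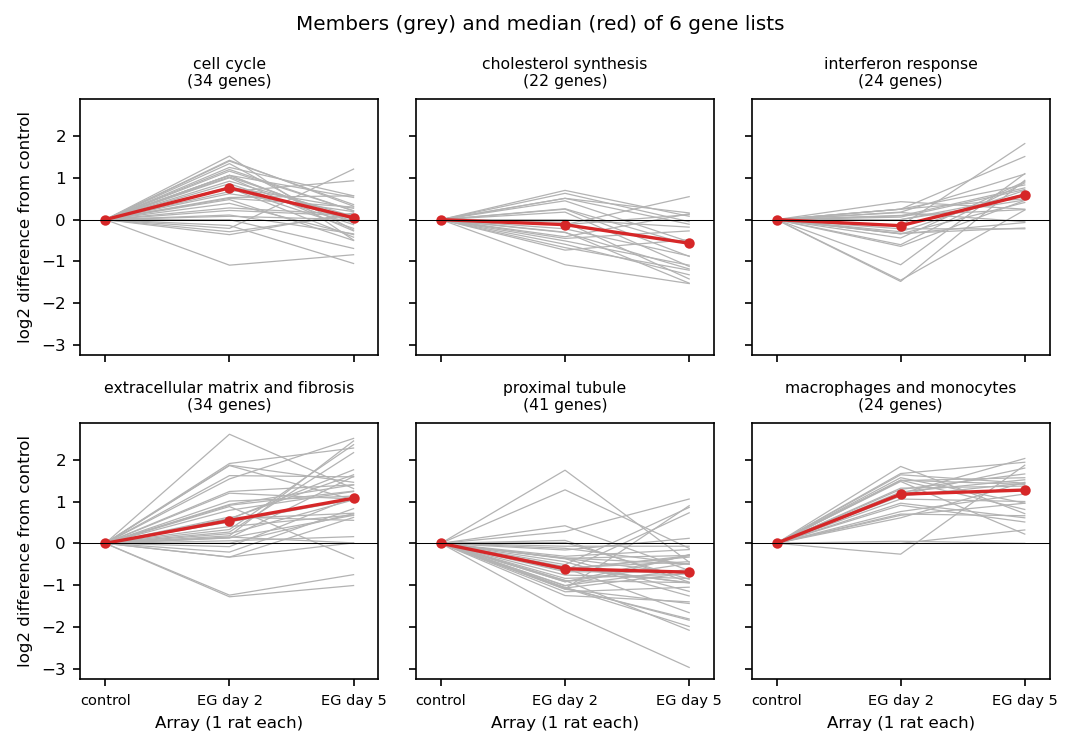
Log2 difference from the control array (vertical axis) on the control, EG day 2 and EG day 5 arrays (horizontal axis, 1 rat each) for the measured members (grey) and the median (red) of 6 lists picked for display after their values were seen. Lines join the same gene across different rats; the cell cycle median is 0.76 at EG day 2 and 0.05 at EG day 5, and the matrix median is 0.55 and 1.08.

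Both time points were compared with the same control array, so their differences share its chance values. Genes at least 2-fold higher at both numbered 227, against 28.7 for independent lists and 36.5 in simulated unchanged arrays that share a control. Genes lower at both numbered 144, against 12.01 and 41.7. Across genes the correlation of the differences from control was 0.60, with 0.50 simulated, and the covariance was 0.21, with 0.11 simulated. A single control array cannot be split, so part of the excess may come from the shared control.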

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

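Of the tests below, the one on collection time was set on clock genes not yet looked at, and the tests on liver tissue, more blood, the acute phase, the clock under treatment, blood content and red cells were chosen after the list results had been seen. The limit of the liver test to transcripts with a difference was also set after their values had been seen.

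The differences of 6 genes from control had opposite directions at the time points, at least 2-fold each way, and the difference between the time points was not tested, with 1 rat each. Dbp was 3.84 log2 units higher at EG day 5 than at EG day 2, Islr, a gene of mesenchymal cells, 2.63 and the interferon-induced gene Rsad2, under background at EG day 2, at least 2.18 (4.53-fold). Sgk1, a kinase gene induced by glucocorticoids and mineralocorticoids, differed by -2.97, Rfk (riboflavin kinase) by -2.47 and Akr1b10 by -2.15. Simulated unchanged arrays gave a mean of 0.09 such genes, against 7 when symbols without a function are counted too. The simulation does not cover genes that vary more between rats than others of like signal, so it does not exclude such variation. Rfk, Sgk1 and Akr1b10 lie outside the naming rule and were chosen after their values were seen.

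Fibrinogen transcripts were high at EG day 2 and much lower at EG day 5. Liver tissue in the kidney piece would bring the abundant hepatocyte transcripts with it, but of 24 that are dim in the control 12 were under background on both arrays, the other 12 had a median difference of 0.22 at EG day 2 (quartiles -0.31 and 0.44), and the highest of the 24 without a background level was 1.10, so the tables argue against it. Erythroid transcripts showed no rise that would go with more blood in the piece. At EG day 2, 13 globins and other erythroid genes had a median of -0.43 (quartiles -0.98 and -0.28), and the 4 globins lay between -1.81 and -0.90. That does not settle the blood content, because fewer young red cells, left open below, would lower such transcripts too. A response shared with other acute phase genes may account for part of the pattern. The acute phase list, which holds no fibrinogen gene, had a median of 1.16 at EG day 2 over 11 of 18 members. The other members, Hpx among them, were under background on all arrays. The highest member, Lcn2 (6.89), is also on the tubular injury and neutrophil lists. Serpina3n (-4.76), Socs3 (-2.70) and Osmr (-1.48) were lower at EG day 5 than at EG day 2. This explanation stays open, because the list still stood at 1.23 at EG day 5, with A2m and Cp higher than at EG day 2 by 1.63 and 0.75. The list median between the time points was -0.40 (percentile 1.61), or -0.24 (percentile 3.42) with the lower background.

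Clock genes, all but Dbp and Nr1d1 chosen after values were seen or for this test, lay apart between the time points, with Dbp, Nr1d1 and Per3 1.94 to 3.84 higher at EG day 5 and Arntl, Npas2 and Nfil3 at -2.76 to -2.02. Collection at different times of day would move other clock genes the same way, and of 6 measured genes of the day phase not yet looked at, 5 were higher, with a median of 0.81 (quartiles 0.33 and 1.45). The exception was Per1 at -0.18, and Bhlhe41 (0.36) and Usp2 (0.32) were higher by little. Ciart was under background on all arrays, and Tef, also set for this test, was not among the genes compared. Bhlhe40, of the same gene family as Bhlhe41 and on the hypoxia list, went the other way, at -0.72. Of genes of the opposite phase not yet looked at, Clock differed by -0.55. Cry1, under background at EG day 5, was lower by at least 0.63. These values go with a different hour of collection, and no label gives one. A change of the clock by the treatment cannot be told apart from that. The 6 day phase genes had a median of -0.57 at EG day 2 against control, and each time is 1 rat.

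Globin transcripts were lower on both EG arrays, with a median difference over 4 genes of -1.33 at EG day 2 and -2.50 at EG day 5. Less blood in the treated pieces would lower other erythroid genes as well, and 9 of these had a median of -0.46 at EG day 5 (quartiles -0.76 and -0.28). The bound set against this explanation, a median above -0.5 with a lower quartile above -1, was met, but by only 0.04 against an interquartile range of 0.48. That bound was poorly chosen, because 3 of the 9 genes lie less than 1 log2 unit above background and could not show a difference of -1, and the demand that the margin exceed the range was added after the values were seen. Less blood and fewer young red cells, for which the globin median of -2.50 is the value at hand, cannot be told apart without a blood count.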

How the results depend on the processing

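Every alternative below was fixed before the data were examined. Leaving out a replicate was not possible with 1 array per group. No paired analysis was possible because each group has 1 rat. Of 96 alternative gene counts 93 stayed within 1.5 times the main count, as did all 16 overlaps. Of 6203 values of named genes under the alternatives 128 moved by more than the estimated noise and 0 of those at least 2-fold apart changed sign. Of 1188 list results 1127 kept their side of the random-list limits, 35 came to stand apart, 26 ceased to, and 0 turned to the opposite side. The other deposited table is identical, so it tests nothing, yet its 12 counts, 785 gene values, 120 list results and 2 overlaps are among the unchanged results above. Median centring left all 120 list results the same. It shifts a list and its random lists nearly alike, so it tests their rank little. Signal over background limits dim genes. The causes of the shifts below were not tested.

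With the background at the median of the olfactory receptor genes, 503 genes were at least 2-fold lower at EG day 2 than in the control (332 in the main setting), and with no background level 601 were. With no level 510 genes were higher at EG day 5 than at EG day 2 (300 in the main setting). Under these lower levels, in that order, lists ceased to stand apart for neutrophils at EG day 2 (0.01 and 0.01) and EG day 5 (0.07 and 0.08), immediate early genes at EG day 2 (-0.15 and -0.085) and smooth muscle at EG day 5 (0.17 and 0.17). Between the time points the same held for acute phase genes (-0.24 and -0.24) and red blood cells (-0.065 and -0.065). Lists that came to stand apart were interferon genes (-0.26 and -0.23) and heat shock genes (0.37 and 0.37) at EG day 2 and liver parenchyma at EG day 5 (0.35 and 0.39). Between the time points they were fibrinogen and coagulation (0.18 and 0.17) and macrophages (0.27 and 0.27).

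With the background at the median of all values, complement at EG day 2 (0.23) and immediate early genes between the time points (-0.28) ceased to stand apart. Fibrinogen and coagulation (0.30) and renin-angiotensin (-0.37) at EG day 2 came to. So did the thick ascending limb (-0.39), fatty acid oxidation (-0.26) and renin-angiotensin (-0.57) at EG day 5, and EG metabolism (0.12) and p53 targets (-0.36) between the time points.

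Intercalated cells at EG day 2 ceased to stand apart with cyclic loess (-0.10), quantile normalization (-0.20) and lists without shared members (-0.14). Cyclic loess and quantile normalization brought out heat shock genes at EG day 2 (0.36 and 0.34) and p53 targets at EG day 5 (-0.26 and -0.28). Cyclic loess also brought out NRF2 genes (0.25) and the unfolded protein response (0.25) at EG day 2.

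Without shared members, calcium genes (-0.01) and immediate early genes (-0.085) at EG day 2, smooth muscle at EG day 5 (-0.11) and fat tissue between the time points (0.34) ceased to stand apart, while the thick ascending limb at EG day 5 (-0.46) and fibroblasts at EG day 2 (-0.44) came to. With the mean of a gene's clusters smooth muscle at EG day 5 (0.31) ceased to and cholesterol synthesis at EG day 2 (-0.16) came to.

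With the mean of a list, the thick ascending limb (-0.13), the respiratory chain (-0.15) and calcium genes (-0.045) at EG day 2 and complement between the time points (0.15) ceased to stand apart. Fibrinogen and coagulation (0.97), interferon genes (-0.24) and renin-angiotensin (-0.46) at EG day 2 and p53 targets at EG day 5 (-0.35) came to. Between the time points so did tubular injury (-0.34), fibrinogen and coagulation (-0.74), p53 targets (-0.45), principal cells (0.21) and the inner medulla (0.21).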

Other observations

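Immediate early genes, which respond within minutes to many stimuli, were lower at EG day 5, when 11 of 24 measured members were at least 2-fold lower and 0 higher than in the control, with a median of -0.60 (percentile 0), including Egr1 (-4.38), Nr4a1 (-3.10) and Zfp36 (-2.75). At EG day 2 the numbers were 8 lower and 1 higher, with a median of -0.19 (percentile 1.23). That median was inside the middle range under 3 alternatives, at -0.15 (percentile 4.32) with the lower background, -0.085 (percentile 10.5) with no background level and -0.085 (percentile 9.17) without shared members. Between the time points the median was -0.31 (percentile 0.84), and -0.28 (percentile 3.54) with the background at the median of all values. Cholesterol synthesis genes were lower at EG day 5, with 8 of 22 at least 2-fold lower, 0 higher and a median of -0.57 (percentile 0). Idi1 differed by -1.53, Dhcr7 by -1.52 and Sc5d by -1.42. At EG day 2 the median was -0.12 (percentile 2.70), or -0.16 (percentile 1.64) with the mean of a gene's clusters, and between the time points it was -0.62 (percentile 0). Cytosolic ribosomal protein genes were higher on both EG arrays, with 9 and 14 of 38 at least 2-fold higher and medians of 0.68 and 0.89 (percentile 100 for both). Rplp0, often used as a reference gene, was higher by 1.33 and 1.70. The reference gene list itself had medians of 0.18 and 0.03 and did not stand apart. Macrophage medians of 1.18 and 1.28 and red blood cell medians of -0.68 and -1.06 stood on the EG day 2 and EG day 5 arrays.

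Genes of oxidative stress and NRF2 had 9 of 35 members at least 2-fold lower and 1 higher at EG day 5 than at EG day 2 (median -0.58, percentile 0), with Gstp1 at -1.39 and Hmox1 at -1.34. Against control their medians were 0.10 and -0.22, inside the middle range, but cyclic loess gave 0.25 (percentile 98.7) at EG day 2. The unfolded protein and integrated stress response list had a median of -0.43 between the time points (percentile 0.31), and 0.24 and 0.00 against control, with Psat1, an enzyme of serine synthesis, at -2.80 at EG day 5. Mitochondrial respiratory chain genes stood at -0.20 at EG day 2 (percentile 1.93), -0.04 at EG day 5 and 0.12 between the time points (percentile 99.9), with 0 of 38 members 2-fold apart. Between the time points the random lists matched to these genes had a median of -0.14. As a mean the EG day 2 value was -0.15 (percentile 6.58), inside the middle range. Calcium, phosphate and vitamin D genes, with 4 of 21 lower and 2 higher at EG day 2, had medians of -0.20 at EG day 2 (percentile 2.26) and -0.20 at EG day 5 (percentile 14.9), with Vdr, the vitamin D receptor gene, at -1.18 and -1.16. Without shared members the EG day 2 value was -0.01 (percentile 28.5). At EG day 2 and EG day 5 the medians were 0.10 and -0.16 for p53 targets, -0.09 and -0.20 for fatty acid oxidation, -0.19 and -0.48 for renin-angiotensin, -0.07 and -0.18 for hypoxia and glycolysis, and 0.30 and 0.09 for heat shock genes. None of these 5 lists stood apart from random lists in the main setting, although all but hypoxia and glycolysis did under at least 1 alternative. Ndrg1 of the hypoxia list differed by -2.58 at EG day 5 and Ppara, a regulator of fatty acid oxidation, by -2.13.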
